A study of Mus musculus with 4 samples.

How the data were processed

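RNA of mouse cortex was compared between 2 ages on 2-colour oligonucleotide arrays. Per the labels, the animals were C57BL6/J mice of 4 or 21 months, and equal amounts of RNA from 3 mice were mixed into 1 pool per age. Both pools went onto every array, one in Cy5 and the other in Cy3, with the dyes exchanged between arrays. The 4 samples of the series are therefore technical repeats of the same 2 pools. No test of age was possible, because each age had 1 pool. Every SD given here is a spread between hybridisations.

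The deposited scanner files hold the median foreground and median local background intensity of each spot in both channels, per the file headers, with a quality flag per spot. They had not been normalised. The 4 files held only 2 distinct scans. The 2 samples labelled with 4-month RNA in Cy5 carried identical values, and so did the 2 samples labelled with 21-month RNA in Cy5. Each scan was counted once. The first scan, labelled with 4-month RNA in Cy5, ended in block 41 of 48 and held 21533 spots. The second scan, labelled with 21-month RNA in Cy5, was complete with 25344 spots. Their median foreground intensities were 2557 and 2797 in Cy5 and 2522 and 2196 in Cy3, against median backgrounds of 1843 and 2372 in Cy5 and 1917 and 1726 in Cy3. The number of arrays limits the precision.

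The deposited table of processed values holds 1 score per spot and array. Per the labels, the authors kept genes with a mean signal over background of at least 1.2 in either condition, fitted a lowess curve with VARAN, and used SAM and a t-test at a p of 5%. The table's rows were matched to probes by the rank of the probe identifier. Under that order the empty cells of 2 columns fell exactly on the 1784 and 1698 spots marked bad in the 2 scans. Pearson's r across spots was 0.883 and -0.840 between these columns and the scans' log2 ratios of Cy5 over Cy3, against 0.0071 and 0.0119, and -0.0123 and -0.0006, with the table shifted by 1 row either way. Across intensity deciles the slope of the scores on the log2 ratio went from 1.77 to 3.08 in size for the first scan and from 1.70 to 3.14 for the second. The scale is thus a stretched log ratio and its base stays unknown. All 4 columns had a median of 0. The scores were used for signs, for limma tests over arrays and for ranks of gene lists, and no fold was taken from them. The other 2 columns belong to arrays whose scanner files were not analysed here.

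Intensities were corrected by normexp with an offset of 50 and normalised within each array by global loess (limma 3.58.1 in R 4.3.3). The 723 control spots had weight 0, and spots with a negative flag were left out. Unflagged spots numbered 7457 and 5295. Spots of 1 probe were averaged, which concerned Actb and Gapdh with 257 spots each. Log2 ratios of both scans were turned to run the same way and averaged. A probe counted as measured when it was unflagged on both scans and its mean signal over background reached 1.2 in at least 1 pool, which held for 3757 of 20458 probes. It passed the size rule with a mean of at least 1.5-fold and the same direction on both scans. Gene names are those of the array design. They were updated through the RefSeq gene table of assembly GRCm38.p6, used for names only: 13895 of 24109 probes carried a current symbol and 7222 more matched 1 gene through an older name.

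The choices above, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Plat and Dbp, the 10 highest and 10 lowest probes with 1 symbol that passed the size rule, and of each list up to 4 members that passed or otherwise the 2 members with the largest ratios. A gene that the rule selects is not reported here. A list's median was taken over genes, with the brightest probe per gene, where at least 5 genes were measured. Its percentile was taken among 10000 random lists of the same size matched on intensity deciles. It describes these pools and is no p-value. Added after seeing the data were limma fits of the 4 score columns with Benjamini-Hochberg adjustment at 0.05, with and without a dye term or the replicate number as a block, and 4 groups of genes described at the end. The dye term was set by the signs of 20 probes with scores beyond 4 on every array, and not by the dye labels.

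The steps were tested on simulated data. With real backgrounds and dye terms and 200 altered probes among 3757, the size rule recovered 43.3% of the probes altered 1.5-fold, 94.0% of those altered 2-fold and 100.0% of those altered 3-fold, and it also took 43 of 3557 unaltered probes. The simulated noise had the same spread for bright and dim probes, so these rates need not hold for the dim ones. For the 4 score columns, limma called 153 of 200 shifted probes and 3 others. The simulated columns had independent noise. Real columns were correlated, with r of 0.357 and 0.422 in 2 pairs and 0.087 to 0.197 in the others, so these rates need not hold. Of 100 simulated lists of 12 genes without a shift, 7 lay outside the central 95% of random lists, and 72 of 100 lists with a log2 shift of 0.3 lay above it. Alternatives covered background correction, normalisation, flags, the filter on dim probes, the size threshold, single arrays and tests over arrays. Other tools were Python 3.11 with numpy, pandas, scipy and matplotlib.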

Results

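Transcript levels in the cortex of young adult and old mice were measured on arrays of long oligonucleotides. The series title names tissue plasminogen activator (Plat), a serine protease, and albumin D site-binding protein (Dbp), a transcription factor of the circadian output pathway, as the genes of interest in ageing. The 4 samples fell into 2 groups of 2 by dye orientation, and 2 distinct scans were behind them, 1 per orientation. Median signal over background of the 3757 measured probes was 2.36 in the pool called P below and 2.75 in the one called Q.

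The age of each pool is not settled by the sources, so the pools are called P and Q throughout. Pool P is the one that the dye labels of the 2 scans give as 21 months and pool Q the one they give as 4 months. The series description states the normalised ratio as 21 over 4 months, and under that statement the signs of the deposited scores make pool P the 4-month pool and pool Q the 21-month pool. Sizes, counts and relative directions below hold under both readings.

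Dbp was 1.47-fold higher in pool P, with a log2 ratio of 0.56 ± 0.15 (SD, n = 2 scans), just under the 1.5-fold rule. Its deposited score also lay towards pool P on 4 of 4 arrays, with a mean of 1.64 ± 0.52 (SD) and a limma adjusted p of 0.00156 over arrays of the same 2 pools. Plat differed little, with a log2 ratio of -0.18 ± 0.04 (SD, n = 2 scans), or 1.14-fold higher in pool Q. Its score pointed to pool Q on 3 arrays and to pool P on 1, with a mean of -0.10 ± 0.34 (SD) and a limma adjusted p of 0.905. Serpine2, an inhibitor of plasminogen activators, had a log2 ratio of -0.04 ± 0.34, and Hlf, a transcription factor related to Dbp, of -0.06 ± 0.33. If the series description gives the direction, Dbp was lower at 21 months. If the dye labels of the scans give it, Dbp was higher. These p-values measure hybridisation error between 2 pools and say nothing on the spread between mice.

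The question of which transcripts differed between the 2 ages was addressed next. Among bright probes, those with a mean log2 intensity of at least 12, 32 passed the size rule towards pool Q and 0 towards pool P. The largest ratios among them were those of probes for a pair of olfactory receptors, the odour-sensing receptors of the nose. Olfr1090 was 2.76-fold higher in pool Q (log2 ratio -1.46 ± 0.03, SD, n = 2 scans) and Olfr1126 was 2.32-fold higher (-1.21 ± 0.31). A probe for the clone 6030402G23Rik, listed under the neuregulin gene Nrg1, was 2.24-fold higher in pool Q (-1.16 ± 0.05), and one for the pseudogene Pisd-ps3 was 2.08-fold higher (-1.06 ± 0.03). All 4 of these probes also scored towards pool Q on 4 of 4 arrays. Olfr805, a dimmer probe, was 2.11-fold higher in pool Q (-1.08 ± 0.45) with the same sign on 4 arrays. No over-representation of olfactory receptor probes was detected among the probes that limma called towards pool Q on the deposited scores, with 11 of 626 against 256 of all 17759 probes (two-sided Fisher's exact test over probes, p = 0.492). As a group they leaned to pool Q all the same, with a median score of -0.02 at percentile 0.05. Of the 626 probes, 81 scored towards pool Q on all 4 arrays and 37 towards pool P, against 1753 and 1426 of all 17759 probes. On the scans 33 of 43 measured olfactory receptor genes were below 0, with a median of -0.17 ± 0.03 at percentile 0.01. The group was drawn up after olfactory receptors had been seen among the largest ratios.

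Over all 3757 measured probes, 89 were higher in pool Q and 30 higher in pool P by the size rule, or 3.17% in all. Pool Q also had the higher median signal over background, and whether that bears on the asymmetry was not tested. Across these probes the 2 scans, turned to the same direction, did not run together, with a Pearson's r of -0.378 and a Spearman's rho of 0.155. Pearson's r was 0.24 over the bright probes and -0.472 over the others, and probes are not independent replicates. The probes furthest towards pool P were Prickle2, Gars (glycyl-tRNA synthetase), Hykk, Dpysl3 (a protein of growing axons), Crat (carnitine acetyltransferase), Zfp202, Casp2 (a caspase), Xpot (a tRNA exporter), Mrps17 (a mitochondrial ribosomal protein) and Cd164. Hykk had a log2 ratio of 1.22 ± 0.16, Casp2 of 0.91 ± 0.31 and Xpot of 0.90 ± 0.34 (SD, n = 2 scans). Without background correction these ratios were 0.37, 0.32 and 0.35, and those of all 10 genes lay between 0.25 and 0.47, below the 1.5-fold rule. Prickle2, at 1.69 ± 2.22, and Mrps17, at 0.86 ± 1.16, differed by less than the spread between scans, as did Crat at 1.07 ± 1.11 and Gars at 1.58 ± 1.75. Towards pool Q the same held for Atp10a (-1.59 ± 2.16), Eml5 (-1.49 ± 1.62) and Mycbp2 (-1.16 ± 1.34). BC064078 had a log2 ratio of -1.11 ± 0.86. Krt31, a hair keratin, was listed at -1.39 ± 0.04 with a signal over background of only 1.14 in pool P, so no fold is given. Without background correction Atp10a, Eml5, Mycbp2, BC064078 and Krt31 lay between -0.39 and -0.23 and did not pass. In all, the mean exceeded the SD for 21 of the 30 probes higher in pool P and 79 of the 89 higher in pool Q. The size rule already asks for the same direction on both scans, which favours this outcome, so these counts are no test of agreement.

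**Figure D1:**
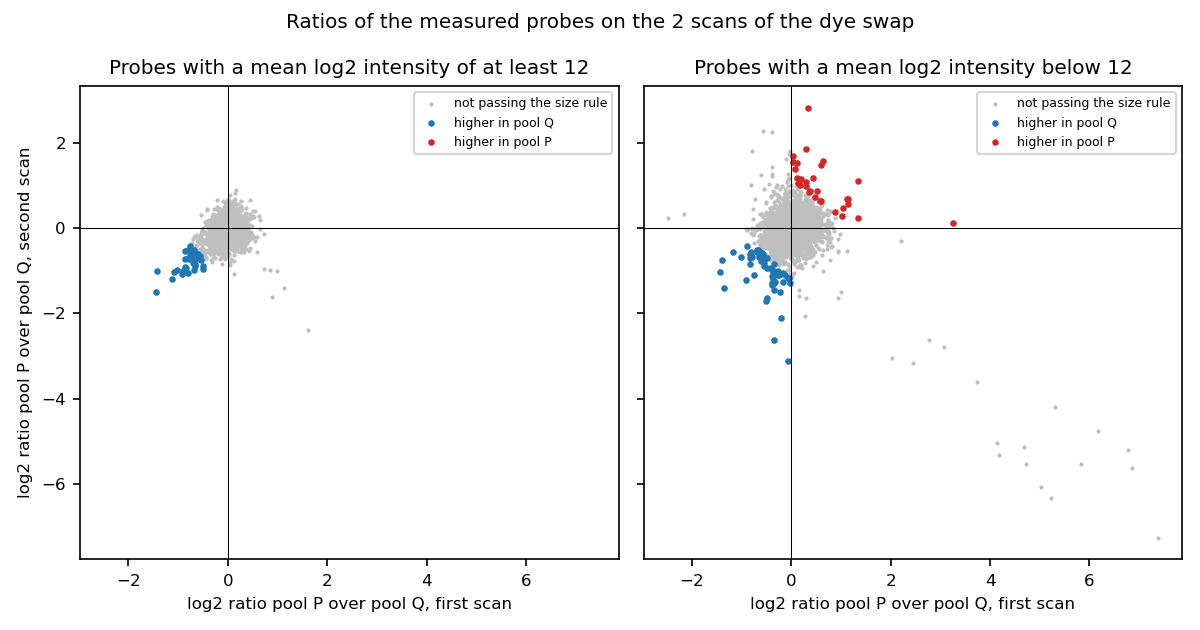
Log2 ratio of pool P over pool Q of each measured probe on the first scan (horizontal) and the second scan (vertical), for probes with a mean log2 intensity of at least 12 (left) and below 12 (right); coloured points pass the size rule. On the left 32 probes stand in the lower left corner and 0 in the upper right, and the points at the far lower right on the right panel follow the dye on both scans. Which pool is 21 months old is not settled.

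The 2 arrays without a scan here gave a separate look at the same pools. Of 81 probes higher in pool Q with scores on both of them, 65 (80.2%) pointed to pool Q on both. Of 23 probes higher in pool P, 11 (47.8%) pointed to pool P on both, close to the 44.2% among measured probes that did not pass the rule. Among dimmer probes, 30 were higher in pool P and 57 in pool Q, while 61 passed the same rule when the dyes rather than the pools were contrasted. Over all measured probes, 0 passed towards pool P and 20 towards pool Q without background correction. limma over the 2 scans called 0 probes after adjustment (72 towards pool P and 196 towards pool Q at an unadjusted p under 0.05). The methods' t-test likewise called 0 (86 and 148 unadjusted), but with 2 scans it has almost no power after adjustment. Keeping all flagged spots gave 730 and 1089 probes against 1459 in the dye contrast.

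The deposited scores of 17759 probes with a value on all 4 arrays showed the same asymmetry. limma called 256 probes towards pool Q and 29 towards pool P at an adjusted p under 0.05. Their median log2 foreground was 12.48 and 12.75, against 11.24 over all 17759 probes, and the stretch of the scores rises with intensity. The calls thus favour bright probes. On the scans 52 of the 256 and 0 of the 29 also passed the size rule. Only 3757 probes were measured there, so some called probes may have had no chance to pass. The columns of the scanned arrays are among the 4 used, so scores and scans are not independent. Outside the rule for named genes, and chosen after their values were seen, probes towards pool P included Txlna (mean score 1.33 ± 0.20, SD, n = 4 arrays), Rgs4, a brake on G protein signalling in neurons (1.08 ± 0.32), Basp1, a protein of axon terminals (1.09 ± 0.42), and Cnp, an enzyme of myelin (0.97 ± 0.25). With the replicate number as a block the counts were 189 towards pool Q and 15 towards pool P, and with a dye term 475 and 148. The calls are of hybridisation error between 2 pools.

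**Figure D2:**
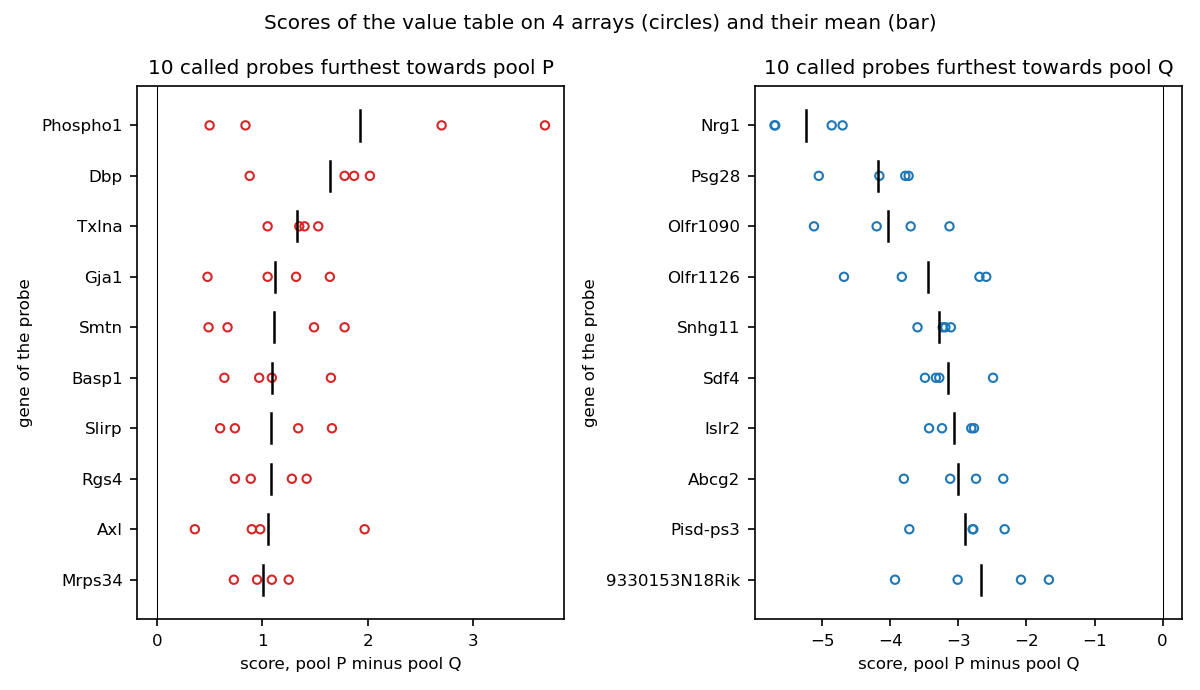
Deposited scores on the 4 arrays (circles) and their mean (bar) for the 10 limma-called probes furthest towards pool P (left) and pool Q (right); the horizontal axis is the score, a stretched log ratio without a known base, positive towards pool P. Dbp stood second towards pool P with a mean of 1.64, and the probe listed under Nrg1 stood first towards pool Q with -5.24. Which pool is 21 months old is not settled.

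Gene lists were compared as groups. Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, leaned towards pool P, with 22 of 23 measured genes above 0, a median log2 ratio of 0.20 ± 0.08 (SD of the median, n = 2 scans) and a median above that of all 10000 random lists (percentile 100.0). None of the 23 passed the size rule. Atp5h had a log2 ratio of 0.42 ± 0.65 and Ndufa8 of 0.34 ± 0.07. Astrocyte genes leaned the same way, with 7 of 8 above 0, a median of 0.15 ± 0.05 and a percentile of 98.92. The glutamate transporter Slc1a3 stood at 0.49 ± 0.13 and the gap junction protein Gja1 at 0.42 ± 0.32. Of 11 myelin and oligodendrocyte genes, 8 were above 0, with a median of 0.15 ± 0.05 and a percentile of 96.84. Gsn stood at 0.32 ± 0.13 and the myelin protein Mog at 0.27 ± 0.38. The medians of these 3 lists stayed above 0 under every background and normalisation setting tried, at 0.13 to 0.20, 0.11 to 0.20 and 0.06 to 0.16. The housekeeping genes Actb and Gapdh also stood towards pool P, at 0.20 ± 0.04 and 0.11 ± 0.07. A lean of this size was thus not confined to these lists.

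On the deposited scores the median of the oxidative phosphorylation list lay at percentile 100.0 (32 genes), the myelin list at 99.97 (17 genes) and the astrocyte list at 99.76 (12 genes). Oligodendrocyte precursor genes lay at 99.36 with 7 genes, choroid plexus genes at 98.87 with 8 and extracellular matrix and meningeal genes at 98.44 with 11. The last list had a median on the other side of 0 on the scans, -0.08 ± 0.11 with 5 genes. Of a group of nuclear long non-coding RNAs drawn up after the data had been seen, 5 of 6 measured genes were below 0 on the scans, with a median of -0.35 ± 0.07. Probes of Malat1, Meg3 and Snhg11 in that group passed the size rule towards pool Q, although the Malat1 probe fell short of it with print-tip loess, at -0.54.

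Apart from oxidative phosphorylation and astrocytes, no list fixed beforehand stood outside the central 95% of random lists on the scans. Immediate early genes, which neurons switch on with activity, had the lowest percentile on the scans among the lists fixed beforehand. Of these genes 4 of 5 were below 0, with a median of -0.22 ± 0.31 and a percentile of 3.86. The direction turned with the choice of spots, as the median of this list of activity-regulated immediate early genes was 0.094 with all spots kept and 0.058 with only bad spots left out, and 1 scan alone gave 0.131. Fosb stood at -0.41 ± 0.01 and Homer1 at -0.32 ± 0.64, and the list lay at percentile 21.6 on the scores with 17 genes. Synaptic genes had a median of -0.04 ± 0.10 with 6 of 16 above 0, where Syt1, the calcium sensor of vesicle release, stood at 0.27 ± 0.05. Their median changed sign among the normalisation settings, from -0.04 to 0.03. Glutamate and GABA receptor genes had a median of 0.11 ± 0.23, with Gabra4 at 0.41 ± 0.22 and Gria2 at 0.25 ± 0.27. Cholesterol synthesis was split 5 to 5, with Lss at -0.48 ± 0.28 and Sqle at 0.41 ± 0.01. Lss scored towards pool Q on 4 of 4 arrays with a limma adjusted p of 0.00305.

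MHC class I and interferon genes were split 3 to 3 with a median of -0.004 ± 0.19. Irf9, an interferon signalling factor, stood at -0.48 ± 0.51 on the scans and scored towards pool Q on 4 arrays (limma adjusted p = 0.00143), while B2m stood at 0.30 ± 0.01. Heat shock genes had a median of -0.02 ± 0.11, with Dnajb1 at 0.46 ± 0.41 and Canx at 0.20 ± 0.15. Antioxidant defence genes had a median of 0.07 ± 0.17 (-0.008 with all spots kept), with superoxide dismutase Sod1 at 0.42 ± 0.38 and catalase (Cat) at -0.40 ± 0.02. Lysosome and autophagy genes had a median of 0.05 ± 0.07, with Map1lc3b at 0.37 ± 0.42 and Ctsd at 0.25 ± 0.10, and a sign that changed with the setting, from -0.002 to 0.063. Genes of young neurons had a median of 0.01 ± 0.09. Dpysl3, at 1.11 ± 0.67, was the 1 gene of all 29 lists that passed the size rule, and Sox11 stood at -0.42 ± 0.05.

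The remaining lists had fewer than 5 measured genes and no median on the scans. In the microglia and complement lists C1qa stood at -0.31 ± 0.47 and Csf1r at 0.19 ± 0.24. Olig1 stood at 0.26 ± 0.09 and Ptprz1 at 0.18 ± 0.87 among precursor genes. Other members stood at 0.13 ± 0.26 for H2-Eb1, 0.31 ± 0.08 for Cck, 0.12 ± 0.35 for Npy, -0.37 ± 0.52 for Ntrk2, 0.31 ± 0.61 for Rgs5 and 0.27 ± 0.16 for Ighm. The senescence markers Cdkn2a and Cdkn1a stood at 0.23 ± 0.70 and -0.23 ± 0.17, and Aplp2 stood at 0.24 ± 0.14. Among markers of neighbouring regions, Ppp1r1b of the striatum stood at 0.09 ± 0.23 and Prox1 of the hippocampus at -0.18 ± 0.23. With 1 measured gene for the striatum and 2 for thalamus and hippocampus, they cannot show whether the dissections matched. On the scores, percentiles were 6.22 for the plasminogen activator system, 78.58 for the circadian list, 71.9 for microglia and 31.54 for complement. The sex-linked list, at 3.74, was the lowest on the scores among the 29 lists fixed beforehand.

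**Figure D3:**
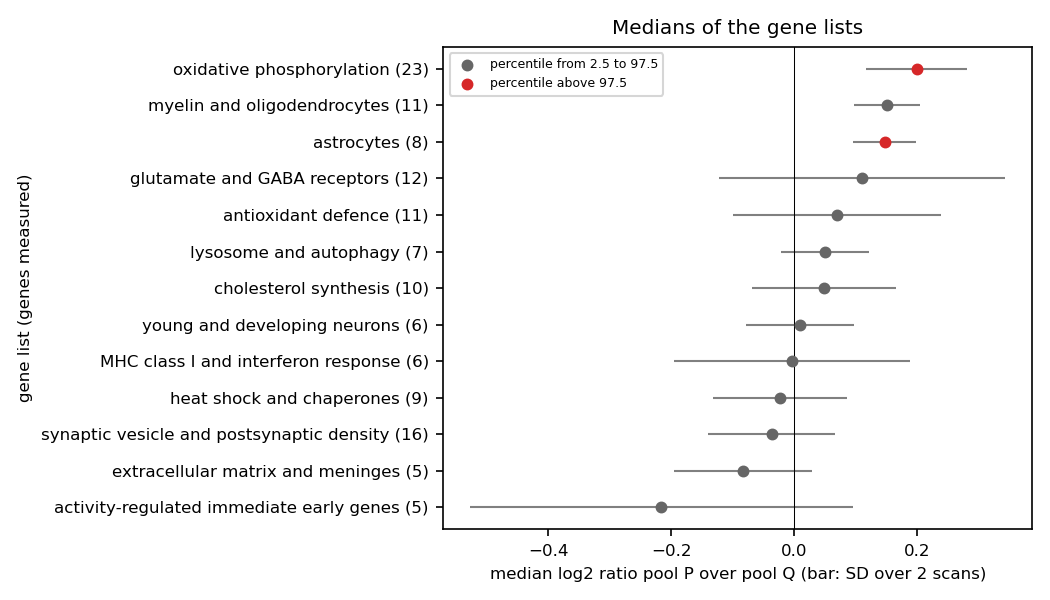
Median log2 ratio of pool P over pool Q of the 13 gene lists with at least 5 measured genes, with the SD of the median over 2 scans as the bar and the number of genes in brackets. Oxidative phosphorylation at 0.20 and astrocytes at 0.15 are the lists whose median lay above the central 95% of matched random lists. Which pool is 21 months old is not settled.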

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

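The fits of the deposited scores, the setting that leaves out only spots marked bad and the turned sign were chosen after the data were seen. Counts are given as pool P and pool Q, against 30 and 89. They stayed within 1.5 times under normexp with offset 16, print-tip loess, median centring and the mean without the rule on single scans. Aquantile scaling leaves the log2 ratios as they are, and the filter on signal over background removed no probe from the 3757 unflagged ones. Aquantile scaling and dropping that filter therefore could not change the counts. The members changed more than the counts with print-tip loess, which kept 20 of the 30 and 72 of the 89 probes. Prickle2 fell from 1.69 to 0.26 there. No background correction gave 0 and 20 and plain subtraction 50 in pool P. All spots kept gave 730 and 1089, and leaving out only bad spots 558 and 900, beside 1459 and 1100 in the dye contrast. A signal over background of at least 2 gave 7 in pool P, 2-fold gave 6 and 14, and 1.3-fold 158 and 292. Leaving out each sample in turn gave 30 to 268 and 89 to 351. A repeated file left out changed nothing, single scans gave 213 to 268 and 308 to 351, and with 1 scan the dye and the pool cannot be separated. limma against 0 gave 0 and 0, and the methods' t-test 86 and 148 unadjusted and 0 and 0 after adjustment, where 2 scans leave it almost no power. On the scores limma gave 256 in pool Q, 148 and 475 with a dye term, and the t-test 643 and 964 unadjusted and 0 and 0 after adjustment. One sign in all 4 columns held for 1426 and 1753, beside 819 and 758 in the contrast between replicate numbers. With the replicate number as a block the scores gave 15 and 189. Same-numbered columns deviated from their group means in opposite directions (r = -0.67 across probes), and crossing the numbers gives the dye-term fit with 148 and 475. With the turned sign the counts read 89 and 30. Dbp kept its side throughout, from 0.45 to 0.67 on single scans. Plat kept its side too, at -0.10 without background correction, -0.13 with print-tip loess and from -0.21 to -0.16 on single scans. Of the named genes and lists none that passed the rule changed sign. In all, 51 of 764 gene values and 11 of 169 list medians moved by more than the SD over scans. The gene values include Aquantile scaling and repeated files left out, which could not move a value. The SD over 2 scans is also wide for some genes, so the fall of Prickle2 to 0.26 did not count as a move. These shares therefore say little on how stable the ratios are. A dye term on the 2 scans was not run, since it leaves no residual degree of freedom, nor a block, since both scans match replicate 2, nor log2 sizes from the scores, whose scale is unknown. Signal over background limits the dim probes, and the cause was not tested for any of these changes.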

Other observations

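The genes in the next 2 paragraphs were chosen after their values were seen. Probes for Malat1, Meg3 and Snhg11, long non-coding RNAs found in the nucleus, passed the size rule towards pool Q. Malat1 was 1.99-fold higher on its dimmer probe (log2 ratio -0.996 ± 0.11, SD, n = 2 scans) and stood at -0.46 ± 0.08 on the brighter. Meg3, an imprinted RNA, had log2 ratios of -0.90 ± 0.07, -0.73 ± 0.31 and -0.38 ± 0.28 on 3 probes, and Snhg11, a neuronal host of small nucleolar RNAs, of -0.84 ± 0.21 and -0.70 ± 0.07 on 2. Neat1 stood at -0.23 ± 0.06, Mirg at -0.18 ± 0.46 and Rian, from the same imprinted region as Meg3, at 0.05 ± 0.23. All of these kept their side of 0 under each of 6 other background and normalisation settings, among them Aquantile scaling, which leaves the ratios unchanged. The passing Malat1 probe fell short of the 1.5-fold rule with print-tip loess (-0.54) and a Snhg11 probe without background correction (-0.50). On the deposited scores 10 of 15 probes of this group pointed to pool Q on all 4 arrays, 8 of them from Malat1, Meg3 and Snhg11, and 0 to pool P. Xist, H19 and Airn scored on both sides.

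Ribosomal protein genes leaned to pool P. On the scans 26 of 42 were above 0 with a median of 0.05 ± 0.04 (percentile 96.06), and 10 of 53 probes scored towards pool P on all 4 arrays against 0 towards pool Q. Of all 17759 probes, 1426 scored towards pool P and 1753 towards pool Q on all 4 arrays. Probes for gene families without known use in cortex (olfactory and vomeronasal receptors, pregnancy-specific glycoproteins and keratins) leaned to pool Q, with 43 of 53 measured genes below 0 and a median of -0.22 ± 0.06. The housekeeping genes Actb and Gapdh stood at 0.20 ± 0.04 and 0.11 ± 0.07.

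The tests on noise, the loess curve, nuclear RNA and dye labels below were chosen after the result was seen. Between pools more probes kept one sign than in any other contrast of the 4 arrays. With a score of at least 0.5 on each array, 208 probes did so (17 towards pool P and 191 towards pool Q). The contrast between replicate numbers gave 2 and its interaction with dye gave 0, while the dye contrast gave 83. The dye contrast was set by the signs of the 20 probes with scores beyond 4 on every array, and not by the labels. With dye set this way, the 2 and 0 argue against noise. If the dye labels are right, the 83 belong to the interaction and the 0 to dye, and the argument is weaker. Without the bound of 0.5 the gap was smaller. One sign was then kept by 3179 probes between pools, 1577 between replicate numbers, 1535 in the interaction and 2660 between dyes. Whether the pools differ by age, by the 3 mice chosen or by RNA preparation was not tested, since each age had 1 pool.

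The lean of the measured silent families to pool Q was weighed next, a group drawn up after olfactory receptors had been seen among the largest ratios. The loess curve is argued against as its source, because with median centring alone the median over the 53 measured genes was -0.24 ± 0.08 and 42 were below 0. Over all 785 probes the families lay at percentile 2.26 with a median score of -0.01. No over-representation among limma's calls was detected (two-sided Fisher's exact test over probes, p = 0.28). The 15 probes that limma called had a median score of -1.23. They were picked for large scores, so this gap cannot show how much of their size a shift of the families gives. A larger share of nuclear or unspliced RNA in pool Q may contribute: ribosomal protein genes lay at percentile 99.83 on the scores, as it would need, but at 96.06 on the scans, and the nuclear RNAs themselves were picked from the same values and decide nothing. It cannot be told apart from an effect of age, since each age had 1 pool.

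A candidate explanation for the unsettled direction is that of dye labels of 2 samples exchanged. On 20 probes with scores beyond 4 on every array, columns that the labels put in 1 orientation shared a sign in 1 probe, while columns with opposite labels but titles of the same kind shared it in 20. The titles separate the arrays the way these dye-driven probes do. If the labels of the replicate 2 samples, whose columns match the scans, are the wrong ones, pool P is the 4-month pool, which is also what the ratio in the series description gives. If those of the replicate 1 samples are wrong, pool P is the 21-month pool, and these probes do not tell the 2 cases apart. The direction remains unsettled.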
